A study of Caenorhabditis elegans with 3 samples.

How the data were processed

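ChIP-seq of GFP-FLAG-tagged EGL-27 was carried out on whole L4 larvae of C. elegans, per the labels, in 3 libraries that the labels give as biological replicates 1, 2 and 4 of 1 technical replicate each. Chromatin was fragmented by sonication, per the labels. The 3 libraries were treated as 1 group. A possible control experiment is named in the labels and was not analysed here.

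Peak lists were used as the authors deposited them, in a format that gives each peak's position, a signal value, a q column and a summit. Each library has its own list, made from its alignment and a control, per the deposited README texts. The pooled relaxed list was made from the 3 alignments together and the control, and the reproducible list was drawn from the pooled and single-library lists by the irreproducible discovery rate (IDR) procedure, per the same texts. The pooled list stops at 30000 peaks. Its deposited name calls it peaks and background as input for IDR, so it holds background by design. How many of its entries are background was not determined, so relaxed-list peaks below cannot be read as weaker EGL-27 sites. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. The signal is the authors' deposited value for each peak, never below 0, on a scale that is not given in the sources used here, and it served only to rank and describe peaks within a list. The q column of the deposited lists was read as a score, because it falls below 0 in some lists (29113 of the pooled ce11 peaks), and was used only in an alternative ranking. Lists exist for the builds ce11 and ce10, per the labels. All results are on ce11 unless ce10 is named, and no coordinates were converted.

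The lists hold 9666 (replicate 1), 13686 (replicate 2) and 6636 (replicate 4) peaks of 460, 430 and 440 bp. Read numbers were not used here, so depth is unknown and list lengths cannot be read as binding strength. Since signals come from lists of different lengths, they were not compared as levels between libraries. Pooling means that a library with more signal can weigh more in the reproducible list. Libraries shared between 2 and 11 identical summit positions with each other, far below their list lengths, so each was counted as its own sample.

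Genome sequence and lengths were those of WBcel235, the same assembly as ce11; no ce11 peak ended beyond its chromosome. For ce10 the WBcel235 lengths were used for chromosome shares. Genes came from Ensembl release 115 (46926 genes, of which 19985 are protein-coding). Coordinates are printed 1-based.

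Peak sets were compared by an overlap of 1 bp or more, with each library's list cut to its 102 highest signals. Chance was estimated from 1000 seeded random placements of the peaks on the same chromosomes. Chromosome shares were tested by exact binomial tests against nuclear genome length, and autosomes were also divided into 3 equal parts. Distances run from the summit to the nearest transcript start. A summit was classed, in this order, as promoter (within 500 bp of a protein-coding start), 5' UTR, coding exon, 3' UTR, intron or intergenic. For gene lists, a summit was assigned to the gene with the nearest start within 2000 bp, and membership was compared by two-sided Fisher's exact tests with genes that any pooled-list peak was assigned to by the same rule. For each RNA class the genes of that class were considered together with protein-coding genes. The 19 lists had at least 3 background members each, and p-values were adjusted over them by the Benjamini-Hochberg method. Of 315 listed symbols, 309 matched the annotation, and 5 of those unmatched were microRNA genes of the heterochronic list. Among these, mir-241 is annotated as cel-mir-241 and has a reproducible peak, which the heterochronic list did not count. Sequences were searched on both strands within 100 bp of the summit. They were compared with windows 1000 bp to the left and right by exact McNemar tests, of which the larger p is given, and with 1000 seeded draws from the 29861 pooled peaks outside the reproducible set. For the transgene, windows of the gene with 20000 bp to each side were ranked among 1000 random windows of the same chromosome.

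Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names egl-27 and unc-119, then the nearest gene of the 25 peaks with the highest signal, then up to 4 members with a reproducible peak per list; further names are marked as chosen after their values were seen. Alternatives covered the overlap rule, list depth, ranking column, build, the upper part of the list by signal, distances, backgrounds and leaving out each replicate. When a replicate was left out, the set was restricted to reproducible peaks in the top lists of both other libraries, since lists could not be made anew without reads. Top lists included mitochondrial peaks, and sets from nuclear top peaks alone were added after seeing the data.

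The gene list test was checked on simulated data, drawing peaks at random from the pooled list over 11961 background genes. In 50 draws, 2 of 950 list tests passed by chance after adjustment (0.211% of tests, in at most 2 draws), and 20 peaks planted at tRNA genes were called in 50 of 50 draws. The planted check covers the tRNA list alone and not lists called on a few members. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.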

Results

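Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where EGL-27 is found along the genome of Caenorhabditis elegans larvae at the L4 stage, the last larval stage before adulthood. EGL-27 is a relative of the vertebrate MTA proteins of the NuRD chromatin remodelling complex and carries a GATA-type zinc finger. The animals carried a transgene that expresses EGL-27 with a C-terminal GFP-FLAG tag in an unc-119 mutant background, and whole animals of mixed sex were used. The data form 1 group of 3 libraries, which the labels call biological replicates 1, 2 and 4. There is no second condition, so the comparisons below are between replicates, between peaks and the genome, and between the reproducible peaks and a longer relaxed list. By its deposited name the relaxed list holds background beside peaks. The labels name a possible control experiment, which was not analysed here. No read counts were used here, so the sequencing depth of each library is unknown and all intervals cover counting error over peaks only.

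The reproducible list, on genome build ce11 (WBcel235), held 102 peaks of 430 bp, which merged into 100 regions covering 43.4 kb. The authors' signal value, which has no stated scale, ran from 18.7 to 45.5 with a median of 22.7. The highest peak (chromosome I, 4171947 to 4172376, signal 45.5) lay between genes, 44 bp from the start of sls-2.4, a gene for the SL2 spliced leader RNA that is joined to downstream messages of operons; its nearest protein-coding gene was egg-5, 573 bp away. The next were in an intron of Y41G9A.17 on the X chromosome (2996893 to 2997322, signal 40.9), in an intron of pqn-41 on chromosome III (1925145 to 1925574, signal 40.5) and between genes on the X chromosome near gtr-1 (806520 to 806949, signal 37.8, 3957 bp from the gene's start) and W02H3.3 (11093952 to 11094381, signal 36.6, 4019 bp from the start). The sixth peak lay in an intron of egl-27 itself (chromosome II, 6842779 to 6843208, signal 36).

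Further peaks among the 25 highest lay in introns of mom-1, a Porcupine relative needed for Wnt secretion (X, 6296298 to 6296727, signal 35.1), of zfp-1, a PHD and zinc finger chromatin protein (III, 8801771 to 8802200, signal 33.2), of let-526, a subunit of a SWI/SNF-type remodelling complex (I, 5316388 to 5316817, signal 30.4), and of mdt-26, a Mediator subunit (II, 5661670 to 5662099, signal 28.2). Peaks between genes lay 2869 bp upstream of sma-9, a zinc finger protein of the body-size TGF-beta pathway (X, signal 32.8), 4884 bp upstream of xol-1, the switch gene of sex determination and dosage compensation (X, 8036214 to 8036643, signal 30.6), and 3006 bp upstream of fos-1, a bZIP factor (V, signal 28.8). The peak near ain-1, a GW182-type protein of microRNA silencing, lay 1043 bp upstream (X, 16612193 to 16612622, signal 30.4). Those nearest to promoters were at tasp-1 (III, 58 bp from the start, signal 31.7), iff-2, an eIF5A gene (II, 44 bp, signal 29.2), and serp-1.1 (X, 288 bp, signal 30.6). The rest of the 25 highest peaks had as nearest protein-coding genes ZK1248.17, F09A5.3, col-94, C30E1.4, K02D3.1, M02F4.2, ppfr-1 and C49F8.15, with signals from 27.4 (C49F8.15) to 33.5 (ZK1248.17). At ZK1248.17 the peak lay 37 bp from the start of another SL2 RNA gene, sls-2.1, and at M02F4.2 it lay 34 bp from a tRNA gene.

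How far the libraries shared these peaks was asked by comparing each library's own list, cut to its 102 highest peaks, with the reproducible list. Of the 102 reproducible peaks, 35 (34.3%) were overlapped by 1 bp or more in replicate 1, 54 (52.9%) in replicate 2 and 41 (40.2%) in replicate 4. In all 3 libraries 12 peaks (11.8%) were overlapped, in 2 or more libraries 36 (35.3%), and in no library 20 (19.6%). The share in all 3 was 5.88% when summits within 100 bp were required and 38.2% with the top 1000 peaks of each list. For the 102 highest peaks, random placement of the same number of peaks on the same chromosomes gave a mean of 0.0157% for all 3 libraries, with a highest value of 1.96% (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). Of the 102 highest peaks of replicate 2, 23 were mitochondrial. With its top list taken among nuclear peaks alone, a choice made after seeing the data, 63 reproducible peaks (61.8%) were overlapped in replicate 2, 40 in 2 or more libraries, 15 in none and again 12 in all 3. With the mitochondrial peaks kept, the libraries' top lists overlapped each other at 18.6% between replicates 1 and 2, 16.7% between replicates 1 and 4, and 24.5% between replicates 2 and 4. The reproducible list was made from these same libraries, so these shares are not an independent test of it.

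Anywhere in the complete lists, 76 of the 102 peaks (74.5%) had a partner in all 3 libraries, 23 in 2 libraries and 3 in 1 library. No reproducible peak lacked a partner in replicate 2, while 14 lacked one in replicate 1 and 15 in replicate 4. The peak near ain-1, for instance, had a signal of 12.1 in replicate 1 and 11.2 in replicate 2 and no partner in replicate 4. The egg-5 and sls-2.4 peak had 13.6, 21.5 and 9.11 in replicates 1, 2 and 4, and the intron peak of egl-27 had 5.92, 14.6 and 12.7. The tasp-1 peak ranked 23 in replicate 2 but 5343 in replicate 1. Across peaks, Spearman correlations of the signal between libraries were 0.10 (replicates 1 and 2, 88 peaks), 0.02 (replicates 1 and 4, 76 peaks) and -0.02 (replicates 2 and 4, 87 peaks). These are across peaks, which are not independent replicates, and the peaks had been selected by their pooled signal. Over all overlapping peaks of the complete lists the correlations were 0.15 (2104 peaks), 0.17 (1218 peaks) and 0.22 (1657 peaks).

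**Figure D1:**
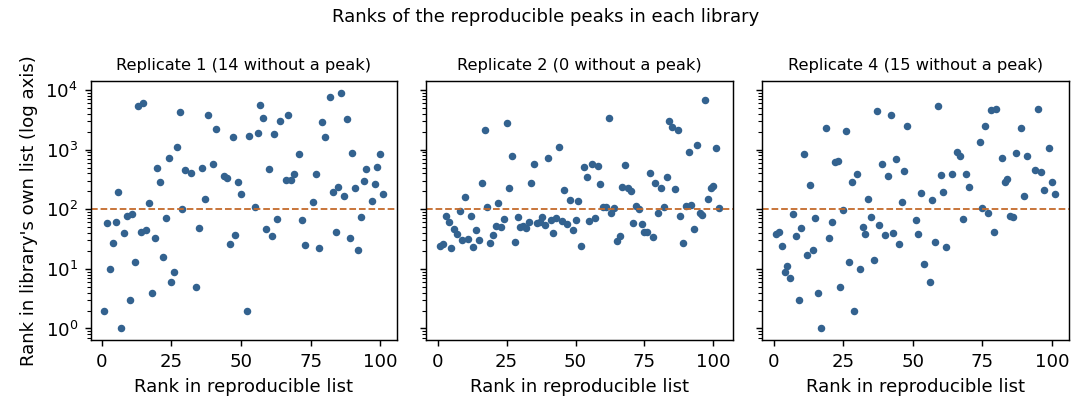
Rank of each of the 102 reproducible peaks in the reproducible list (horizontal axis, by the authors' signal) against its rank in the own list of replicates 1, 2 and 4 (vertical log axes), with a dashed line at rank 102. Points below the line number 35, 54 and 41 by overlap with the top lists, and peaks without a partner (14, 0 and 15) are not drawn; ranks in replicate 2 count its mitochondrial peaks.

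The X chromosome held more reproducible peaks than its length accounts for. It carried 31 of 102 (30.4%, 95% exact binomial interval 21.7 to 40.3%) against 17.7% of nuclear genome length, a 1.72-fold excess (exact binomial test, two-sided, adjusted p = 0.00977 over 6 chromosomes). Chromosome IV carried 10 (9.80% against 17.4% of length, adjusted p = 0.147 by the same exact test), and chromosomes I, II, III and V carried 11, 14, 19 and 17 peaks. In the pooled relaxed list the X chromosome held 18.5% of 30000 peaks. Among the autosomal peaks 35 of 71 (49.3%, interval 37.2 to 61.4%) lay in the central of 3 equal parts of their chromosome, against 33.3% of length (exact binomial p = 0.00546), and the relaxed list had 37.1% there. Neighbouring peaks are not independent, so these p-values are somewhat too small. With only the 20 peaks that were in the top lists of both replicates 1 and 2 (replicate 4 left out), the X share was 40.0% and the adjusted p by the exact binomial test rose to 0.0954; with the mitochondrial peaks left out of replicate 2's top list it was 10 of 24 peaks (41.7%, adjusted p = 0.031 by the same exact test). Without the 13 peaks assigned to tRNA genes, a setting chosen after seeing the data, 22 of 89 peaks (24.7%) were on the X chromosome, 1.40-fold its length share (exact binomial adjusted p = 0.188).

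**Figure D2:**
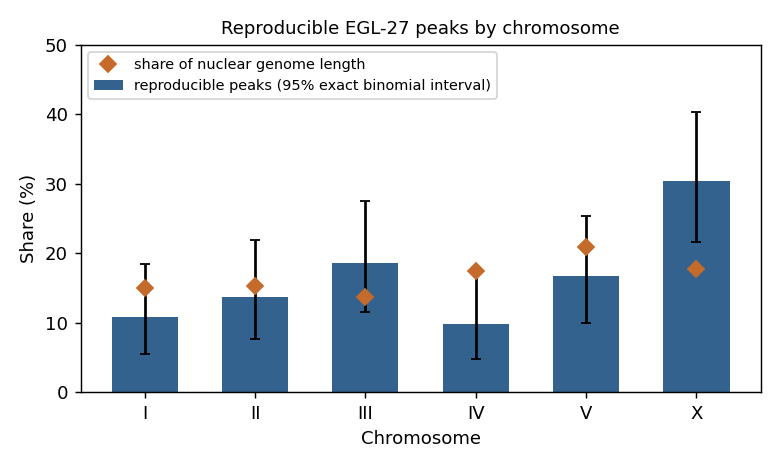
Share of the 102 reproducible peaks on each chromosome (bars, percent, with 95% exact binomial intervals) beside each chromosome's share of nuclear genome length (diamonds). The X chromosome bar stands at 30.4% against 17.7% of length, and its interval (21.7 to 40.3%) is the only interval that lies wholly above its diamond; that of chromosome IV lies wholly below.

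Relative to protein-coding genes the reproducible peaks were not detectably closer to transcription start sites than chance at 500 bp. In all, 29 of 102 summits (28.4%) lay within 500 bp of such a start, against 22.5% ± 4.15 (SD over 1000 random placements, permutation p = 0.188, two-sided) and 28.1% of relaxed-list summits. The direction turned in the upper 51 peaks by signal (21.6% against 21.8% at random) and in the 16 to 24 peaks left without a replicate (6.25 to 12.5% against 20.5 to 21.8%), none of which passed the test. When starts of all annotated genes were counted, short RNA genes included, 59.8% lay within 500 bp, against 32.3% of random placements (permutation p = 0.002, the smallest two-sided value) and 39.7% of relaxed-list summits (permutation p = 0.002). Within 200 bp of a protein-coding start lay 17.6%, against 9.73% at random (permutation p = 0.024) and 13.9% in the relaxed list (permutation p = 0.316). A coding exon held 1 summit (0.980% against 17.5% at random, adjusted permutation p = 0.012), introns held 29, and 43 lay between genes (42.2% against 30.6%, adjusted permutation p = 0.042). No summit lay in a 5' or a 3' UTR.

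Peaks on the X chromosome lay farther from protein-coding transcription start sites than those on autosomes. On the X chromosome 3 of 31 summits (9.68%) were within 500 bp of a protein-coding start, with a median distance of 2644 bp, against 26 of 71 (36.6%) on the autosomes, with a median distance of 789 bp (Fisher's exact test, two-sided, odds ratio 0.188, p = 0.00774). This comparison was not among the tests fixed beforehand, and its p-value is unadjusted. In the relaxed list the shares were 23.3% and 29.1%. Taken alone, a choice made after seeing the data, the autosomal peaks exceeded random placement (23.9%, permutation p = 0.02), and the X peaks lay below it without passing the test (18.8%, permutation p = 0.304).

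Genes for short structural RNAs were over-represented beside the reproducible peaks. Of 71 genes assigned a peak when tRNA genes were counted with protein-coding genes, 13 were tRNA genes, against 3.04% of background genes (odds ratio 7.37, 95% interval 3.67 to 13.8, Fisher's exact test, adjusted p = 3.42e-06 over 19 lists). For the 4 tRNA genes with the highest peak signal, all on the X chromosome, the distance from the summit to the gene's start was 1506 bp (WBGene00014538, signal 36.6), 1422 bp (WBGene00022952, signal 31.4), 328 bp (WBGene00022939, signal 30.6) and 34 bp (WBGene00023110, signal 29.6). With the assignment limited to 500 bp, 10 tRNA genes remained (odds ratio 8.63). Of the 13, 9 were on the X chromosome, which holds 45.1% of nuclear tRNA genes. Within the X chromosome alone, a setting chosen after seeing the data, the odds ratio was 10.7 (Fisher's exact adjusted p = 7.85e-05). Within the autosomes alone it was 4.05 with 4 genes and did not pass (Fisher's exact adjusted p = 0.135).

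Small nuclear and nucleolar RNA genes gave 10 of 67 assigned genes, against 2.23% of background genes (odds ratio 7.96, interval 3.58 to 15.9, Fisher's exact adjusted p = 1.96e-05). In order of peak signal the leading members were sls-2.4 (signal 45.5), C04A2.16, which lies inside the egl-27 gene (36), sls-2.1 (33.5) and R07E5.16 (31.7). Further members, chosen after their values were seen, were sls-2.3, sls-2.8 and sls-2.16, and 5 of the 18 annotated SL2 RNA genes and 0 of the 12 genes annotated as SL1 RNA genes had a reproducible peak. How many SL1 RNA genes had a relaxed-list peak was not counted, so the 0 does not show a difference between the families. Without the SL2 RNA genes, a setting chosen after seeing the data, the list no longer passed (odds ratio 3.87, 5 members, Fisher's exact adjusted p = 0.0595). None of the 10 was on the X chromosome. Genes of both RNA classes have near-identical copies: of the 36-base words inside those under the peaks, 53.3% occurred at a single place in the genome.

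Among protein-coding gene lists, 2 passed. Of the heterochronic list, genes that time larval development, 3 members had a reproducible peak: ain-1 (signal 30.4), lin-66 (IV, 13887477 to 13887906, signal 24.1, 387 bp from the start) and lin-14 (X, 11481583 to 11482012, intron, signal 20.2). The odds ratio was 63.7 (interval 10.8 to 263, Fisher's exact adjusted p = 2.06e-04), over 12 background members. At an assignment distance of 500 bp 1 member remained (adjusted p = 0.143 by Fisher's exact test), and none of the 3 was among the peaks shared by the top lists of any pair of libraries while mitochondrial peaks took 23 places in that of replicate 2. Among nuclear top peaks ain-1 was shared by replicates 1 and 2 (odds ratio 108, interval 2.29 to 888, Fisher's exact adjusted p = 0.0696). The translation factor list had iff-2 (signal 29.2) and eef-1G (V, 10965475 to 10965904, 29 bp from the start, signal 24.3), with an odds ratio of 14.5 (interval 1.63 to 60.0, Fisher's exact adjusted p = 0.0477). Neither was in the shared peaks when replicate 2 or replicate 4 was left out.

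The other lists did not pass over all 102 peaks. MicroRNA genes had 3 members, mir-54 (signal 32.8, 301 bp from the gene's start), mir-71 (28.7, 1808 bp) and mir-241 (23.9, 362 bp), with an odds ratio of 4.03 (interval 0.799 to 12.5, Fisher's exact adjusted p = 0.166). In the upper 51 peaks by signal this list did pass, as 1 of 5 lists. Nuclear hormone receptors had nhr-3 and nhr-105 (odds ratio 2.22, interval 0.261 to 8.47). There was 1 member each for NuRD and synMuv chromatin (egl-27, odds ratio 11.6, interval 0.272 to 76.8), cuticle collagens (col-94, odds ratio 1.59, interval 0.0392 to 9.34), stress and ageing (xbp-1, odds ratio 5.98, interval 0.145 to 37), ribosomal proteins (rpl-6, odds ratio 3.13, interval 0.0769 to 18.8) and histones (his-37, odds ratio 14.3, interval 0.331 to 97.7). The lists of Hox and Wnt pathway, GATA factor, epidermis and seam cell, intestine, muscle, neuron, germline, and vulva and EGF or Notch genes had 0 members. Their upper limits of the odds ratio ran from 26.4 (muscle) to 129 (GATA factors), so over-representation could not be excluded for them at this number of peaks. Only 69 of the 102 summits lay within 2000 bp of a protein-coding start, and the other peaks entered no protein-coding list. Among those left out was the intron peak of mom-1, 3401 bp from the start, a gene that was not on the Hox and Wnt list.

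**Figure D3:**
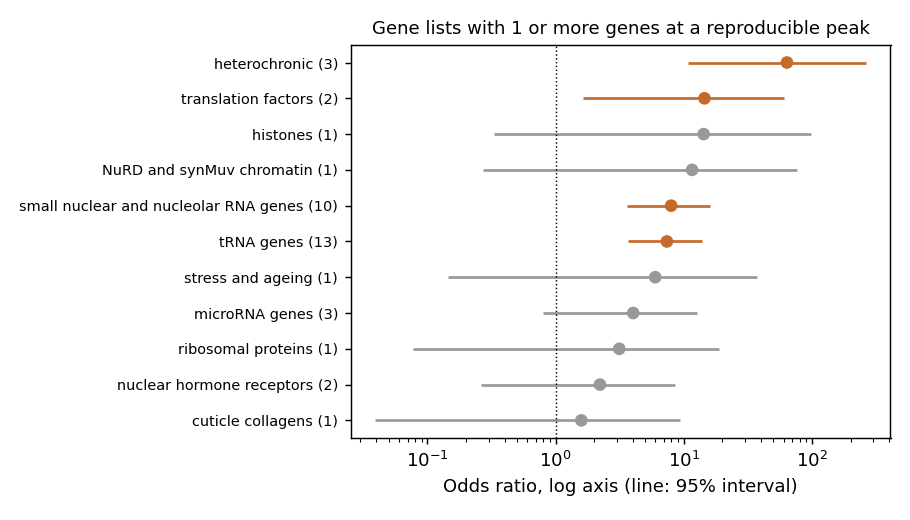
Odds ratios (log axis, lines for 95% intervals) of the 11 gene lists with at least 1 gene at a reproducible peak, with the number of member genes in brackets and lists with adjusted p under 0.05 in orange. The tRNA genes (7.37) and the small nuclear and nucleolar RNA genes (7.96) have the narrowest intervals among the 4 orange lists.

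EGL-27 carries a GATA-type zinc finger, and GATA factors recognise the sequence WGATAR (W is A or T, R is A or G). This sequence was not more frequent under the summits: 31 of 102 windows of 100 bp to each side had it (30.4%, interval 21.7 to 40.3%), against 36.3% of windows 1000 bp to each side (exact McNemar p = 0.451) and 37% around relaxed-list summits (permutation p = 0.17). TGATAA was present in 11.8% of windows, against 20.1% of flanks and 18.8% around relaxed-list summits (exact McNemar adjusted p = 0.336, permutation adjusted p = 0.134).

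The sequence GAGAGA stood out among the 8 searched. It was present in 47 of 102 windows (46.1%, interval 36.2 to 56.2%), against 13.7% of flanks (exact McNemar adjusted p = 1.12e-04) and 14% around relaxed-list summits (permutation adjusted p = 0.00533). Its share was 35.5% on the X chromosome and 50.7% on the autosomes. CACGTG (12.7% against 2.94% of flanks and 3.93% of relaxed-list summits) and GGGCGG (11.8% against 3.92% and 3.75%) passed against the relaxed list (permutation adjusted p = 0.00533 for both) but not against the flanks (exact McNemar adjusted p = 0.0851 and 0.205). TTTCAAA was less frequent than in the relaxed list (12.7% against 26.4%, permutation adjusted p = 0.008). It passed against the left flank (28.4%, exact McNemar adjusted p = 0.0453) but not the right (22.5%, exact McNemar adjusted p = 0.176). By the larger p it did not pass against the flanks (25.5%, exact McNemar adjusted p = 0.22). GTAAACA and TGACTCA were present in 0.980% and 1.96% of windows and passed neither test.

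**Figure D4:**
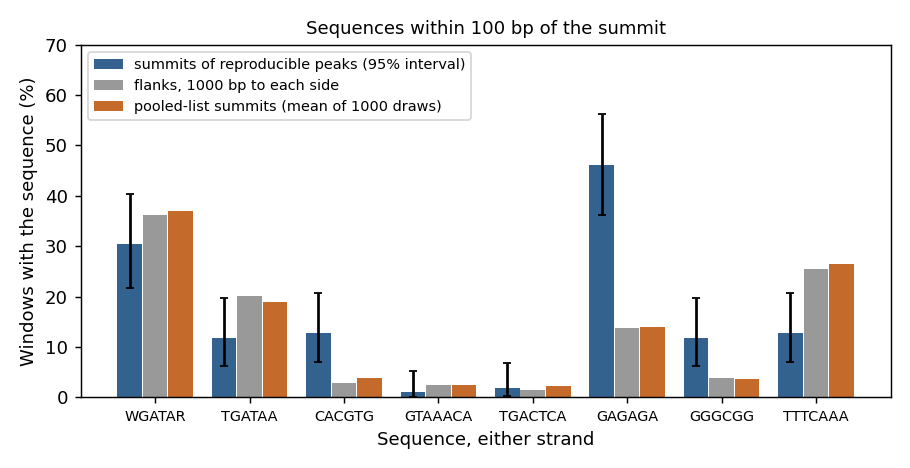
Share of windows of 100 bp to each side (percent) with each of 8 sequences on either strand, for summits of the 102 reproducible peaks (blue, 95% exact binomial intervals), for flanks (grey) and for relaxed-list summits (orange, mean of 1000 draws). GAGAGA stands at 46.1% against 13.7% and 14%, while WGATAR stands at 30.4% against 36.3% and 37%.

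The gene carried by the transgene was examined separately, since sequence present in extra copies can give more reads. The window of egl-27 (II, 6835008 to 6847908, plus strand) and 20000 bp to each side held 4 reproducible peaks: introns of egl-27 at 6836723, 6839027 and 6842779, and a peak at 6849252 whose nearest gene was tbc-6. The pooled relaxed list had 46 peaks there, against a median of 16 in random windows of the same width on the chromosome (percentile 99.85 by number and 99.8 by summed signal). Replicates 1, 2 and 4 had 28, 22 and 30 peaks there, against random medians of 5, 7 and 3. The window of unc-119 (III, 10902641 to 10908935, plus strand), the gene mutated in the strain, held 0 reproducible peaks and 13 relaxed-list peaks, at percentile 29.6 by summed signal.

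**Figure D5:**
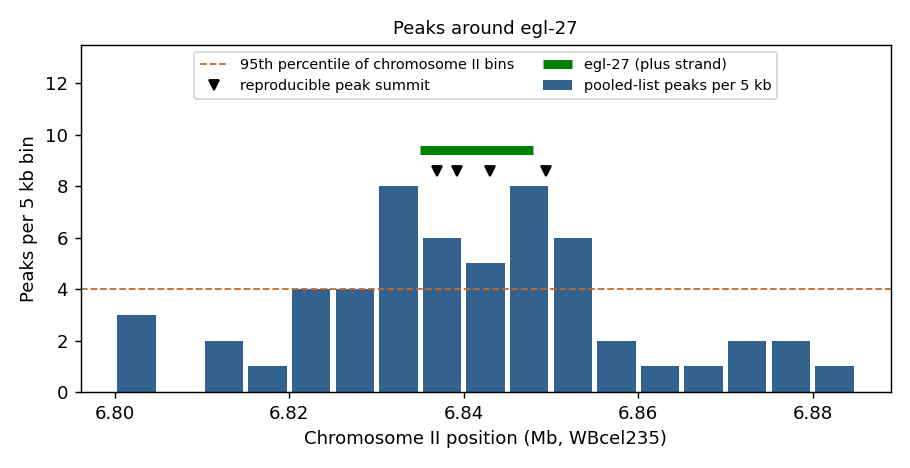
Number of pooled relaxed-list peaks per bin of 5000 bp along chromosome II around egl-27 (bars; horizontal axis in Mb), with the gene (green bar), the summits of 4 reproducible peaks (triangles) and the 95th percentile of the chromosome's bins (dashed line, 4 peaks). Bins from 6830001 to 6855000 hold 5 to 8 peaks each.

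The lists were also given on the older build ce10, where the reproducible list held 70 peaks with signals from 21 to 45.5. Each of the 70 signals had a ce11 counterpart within 0.01, and with the same tolerance 70 ce11 peaks had a signal at or above the lowest ce10 value. In both builds the reproducible list held as many peaks as the pooled list has at or above its lowest signal (102 and 70), so the lists differ by where the ranking stops. The X chromosome held 25 of the 70 ce10 peaks (35.7%).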

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

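The test of X coverage, the test of tRNA gene density on the X chromosome and the test on ribosomal protein genes were chosen after the results were seen. The bound on the shared-read test and the test of the peaks that do not overlap their gene were also added after its result. The others were written before their result was known.

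Mitochondrial DNA gave peaks in 1 library alone. The list of replicate 2 held 23 mitochondrial peaks, where the lists of replicates 1 and 4, the pooled list and the reproducible list held 0. A count of 0 allows up to 3 only for independent counts, which neighbouring mitochondrial peaks are not. The pooled list held 0 although the alignment of replicate 2 went into it, and the reason was not tested. Their signals ran from 14.1 to 335, while the highest nuclear peak of that library had 22.5, and they covered 55.6% of the mitochondrial genome. They entered the agreement between libraries, since 23 of the 102 highest peaks of replicate 2 were mitochondrial. They also took places in the top lists behind every set with replicate 1 or 4 left out. Dropping them, a choice made after seeing the data, left the share of peaks overlapped in all 3 top lists at 11.8%, raised that in replicate 2 from 52.9% to 61.8%, and added 4 peaks to the 20 shared by replicates 1 and 2 and 0 to the 24 shared by replicates 2 and 4.

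For the excess of reproducible peaks on the X chromosome, higher coverage along the whole chromosome could not be settled. The X share of the relaxed list, 18.5%, lies below the lower limit of 21.7% in the reproducible list. But the reproducible list holds only the upper end of the relaxed list by signal (102 peaks). A rise along the chromosome could shift the highest peaks more than the whole list, so the comparison cannot decide. The number of tRNA genes on the X chromosome cannot be told apart from the excess: without the peaks assigned to tRNA genes the X share was 24.7% (interval 16.2 to 35.0%), and the fold fell from 1.72 to 1.40, with fewer peaks to test. Of the 9 X peaks removed there, 2 also hold the element described next, so these explanations share peaks. The tRNA gene peaks and the peaks with the element were each left out alone, never together. The X shares that remained, 24.7% and 23.3%, therefore do not show an excess beyond both sets. Recruitment sites of the dosage compensation complex, which lowers X expression in hermaphrodites, were a candidate explanation that could be tested by sequence: the element TCGCGCAGGGAG, taken from general knowledge of that complex, with at most 2 mismatches, was inside 10 of 31 X peaks (32.3%, interval 16.7 to 51.4%) and 2 of 71 autosomal peaks (2.82%, interval 0.343 to 9.81%; Fisher's exact p = 8.61e-05), and inside 0.889% of the relaxed-list X peaks outside the set. Mapped recruitment sites were not compared, so whether these matches are such sites stays open. Whether EGL-27 itself is at the matches, or they are recovered in many ChIP-seq experiments, stays open too, since no other factor or control was analysed here.

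Peaks at tRNA, snRNA and snoRNA genes, part of whose sequence occurs more than 1 time in the genome, may in principle come from reads that fit several copies. The test made for this could not decide it: a median of 95.4% of the 36-base words in the 24 peaks at these genes occurred at a single place in the genome, but the genes fill so little of a peak that genes shared throughout would still have left 90.5%. Of the words inside the genes themselves, 53.3% occurred at a single place, so shared reads stay open for the 18 peaks that overlap their gene. The other 6 do not overlap their gene, whose start lay 246 to 1930 bp from the summit. A median of 0.0% of their words occurred more than 1 time, so reads inside them fit a single place. Reproducible peaks away from these genes also had a median of 100% single words. The result was thus nearly fixed by leaving the gene out, and it is no test of the gene copies. A general recovery of strongly transcribed genes stays open too: the ribosomal protein list did not pass (Fisher's exact p = 0.279), but the upper limit of its odds ratio, 18.8, does not exclude an excess as large as that of the tRNA genes, and no biological explanation was tested for these peaks.

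The peaks at egl-27 may reflect extra copies of the locus brought by the transgene. The number of relaxed-list peaks within 20000 bp of the gene was at percentile 99.85 of the chromosome's windows. Extra copies would give this, but so would EGL-27 at its own gene, so the value cannot tell them apart. The window of unc-119, chosen beforehand as a region that may also be in extra copies, was not raised (percentile 36 by number). Which unc-119 sequence the transgene carries was not examined here, so this value does not bear on extra copies of egl-27. Raised bins of the pooled relaxed list ran from 6830001 to 6855000, 25 kb, beyond both ends of the gene and into tbc-6, dnj-5 and C04A2.15. The last of them, from 6850001, alone reached dnj-5 and C04A2.15. It held 6 pooled peaks but only 1, 2 and 1 in replicates 1, 2 and 4, so that edge rests on the pooled list. Outside the block the highest bin of the chromosome held 7. The extent of the genomic fragment in the transgene and the origin of the control are not given in the sources used here, so EGL-27 at its own gene stays open beside extra copies.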

How the results depend on the processing

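Alternatives that split peaks by chromosome, or left out mitochondrial peaks, egl-27, the tRNA gene peaks, SL2 RNA genes or peaks with the 12-base element, were chosen after seeing the data. Replicate agreement (5.88% with summits within 100 bp, 38.2% with the top 1000 peaks) and the egl-27 and unc-119 windows of the pooled list kept their direction and side of the threshold in every setting run. The tRNA list did so except on autosomes alone (odds ratio 4.05), and the small nuclear and nucleolar RNA list except without SL2 RNA genes (3.87) and on the X chromosome alone (0.0, upper limit 29.7, 0 of 13 genes). With a replicate left out their odds ratios were 10.7 to 23.1 and 19.8 to 88.9. Leaving out a replicate leaves only 16 to 24 peaks by construction, which limits every test on them. In the list of replicate 1, the unc-119 window with 5000 bp to each side turned to percentile 83.2 by number (3 peaks against a random median of 1).

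By construction the upper part of the reproducible list has 51 peaks. The X share was 40.0% with adjusted p = 0.0954 (exact binomial) without replicate 4, within 40.0 to 56.2% over the replicates left out, 24.7% without the tRNA gene peaks and 23.3% without the peaks that contain the element; it passed in the other settings, among them replicate 4 left out with nuclear top peaks (41.7%). The share of summits near protein-coding starts exceeded chance within 200 bp (17.6%), with starts of all genes (59.8%) and on autosomes alone (36.6%). It fell below chance, without passing, in the upper 51 peaks (21.6%), on the X chromosome alone (9.68%) and with each replicate left out (6.25 to 12.5%); apart from the smaller sets, the cause was not tested. The number of gene lists passing was 4, 3 at 500 bp (heterochronic lost), 5 in the upper 51 peaks (microRNA genes gained), and 2 to 3 with a replicate left out (2 without replicate 2, and 2 without replicate 4 with or without mitochondrial peaks). The heterochronic odds ratio was 34.5 at 500 bp (adjusted p = 0.143, Fisher's exact) and 0.0 to 0.0 with any replicate left out. Without replicate 4 that 0.0 rests on the mitochondrial peaks in the top list of replicate 2: among nuclear top peaks ain-1 was shared and the odds ratio was 108 (adjusted p = 0.0696, Fisher's exact). The translation factor odds ratio ran from 0.0 (without replicate 2 or 4) to 82.9. WGATAR was in 71.6% of the widest windows searched, above its flanks but not past the test. The other sequences, GAGAGA among them, were not run in any alternative setting. Depth was unknown, so no setting could address it. No paired analysis was possible because there is 1 group.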

Other observations

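The genes and peaks named here were chosen after their values were seen. Besides the SL2 RNA genes, several reproducible peaks lay within 50 bp of a tRNA gene start: WBGene00023051 (X, 21 bp, signal 26.4), WBGene00004708 (X, 30 bp, signal 23.6), WBGene00023038 (IV, 32 bp, signal 20.9), WBGene00014331 (V, 19 bp, signal 20.2), WBGene00022947 (X, 20 bp, signal 19.4) and WBGene00022911 (IV, 16 bp, signal 19.3). SL2 RNA genes taken alone gave 5 of 67 assigned genes against 15 of 12169 in the background (odds ratio 97.0, interval 25.3 to 323).

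The 4 strongest X peaks, near Y41G9A.17, gtr-1, W02H3.3 and mom-1, each contained the 12-base element with at most 1 mismatch, and those at Y41G9A.17 and W02H3.3 contained it with 0 mismatches. The peak upstream of xol-1 contained it with 1 mismatch. Without the peaks that have the element, 21 of 90 were on the X chromosome (23.3%, interval 15.1 to 33.4%, exact binomial adjusted p = 0.333).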
